A study of Mus musculus with 2 samples.

How the data were processed

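The series holds single-cell RNA sequencing of red cell progenitors from the fetal liver of C57BL/6 mouse embryos at embryonic day 14.5, when the liver is the main blood-forming organ. A burst-forming unit-erythroid (BFU-E) is an early progenitor committed to the red cell lineage, and a colony-forming unit-erythroid (CFU-E) is a later one. Per the labels, the cells were low in CD71 (the transferrin receptor, encoded by Tfrc) and CD24 (encoded by Cd24a), and a 10x 3' version 3 kit was used. This chemistry reads the 3' end of a transcript and tags each molecule with a unique molecular identifier (UMI). The hashed library pooled cells of 4 isolations that carried different antibody-linked barcodes, which the labels name FACS BFU-E, FACS CFU-E, PE-low and PE-high. FACS is fluorescence-activated cell sorting. The labels speak of a magnet method beside FACS, so PE-low and PE-high were taken to be its fractions. The CITE-seq library held cells stained with barcoded antibodies against CD117 (encoded by Kit) and CD71. Its cells carry the names CS BFUE, CS CFUE or unknown in the deposited cell table. What PE and CS stand for, and how cells were assigned to names, is not given in the sources used here. The labels also describe 10 days of growth in medium with dexamethasone, a glucocorticoid, at 100 uM or with methanol. Whether the sequenced cells went through this is not given in the sources used here, and treatment was not analysed.

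The authors deposited 1 table of natural log values with cells against Ensembl gene IDs for both libraries together. Each value is the natural log of 1 plus the count per 10000 of the cell, as the values themselves show: with the log undone, each cell sums to 10000. Per the submitters' processing notes, Cell Ranger 4.0.0, Scanpy and build mm10 were used. The filters on cells and genes are not given in the sources used here. The authors also deposited 2 principal component coordinates per cell, a score called corrected in the file header. They were not used here, and what they were corrected for is not given in the sources used here. UMI counts were recovered by dividing each cell's linear values by the smallest nonzero value of the cell. All of 16419767 nonzero values (100%) came out whole within 0.02. The table held 3357 cells and 17608 genes, of which 352 were at 0 in all cells. A symbol was found for 17592 IDs, 16 had none, and 10 kept their ID because their symbol was shared. Gene positions are from the RefSeq annotation of GRCm38.p6, the assembly that mm10 denotes. Cell barcodes ended in 1 of 2 suffixes. All cells with the name of a hashed pool shared 1 suffix, so the cells with it, 2 of them named unknown, were placed in the hashed library. Cells with the other suffix were placed in the CITE-seq library by elimination.

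A pool is the set of cells with 1 name, and each pool is 1 sample. Cells are not replicates, so no test between pools, p-value or standard error was computed, and no difference below has a replicate check. UMIs were summed per gene over the cells of a pool and scaled to a common total per pool, in the unit CPM. A gene entered a comparison with at least 50 CPM in a pool of the pair and a UMI in at least 10% of the cells of a pool of the pair. A gene under 50 CPM in 1 pool could thus enter only by being higher in the other. For such genes the direction follows from the filter, which limits counts of list members in 1 direction. Genes are said to lie past 1.5-fold where the ratio of the pool levels was at least 1.5 either way, a fixed size and not a test. Ratios carry 95% exact conditional binomial intervals, levels 95% exact Poisson intervals and shares of cells 95% exact Clopper-Pearson intervals. All of these cover counting error only. A side at 0 UMIs was set to 3 counts of its pool's total, which was 0.407 CPM in FACS BFU-E, 0.481 in FACS CFU-E, 0.423 in PE-low, 0.273 in PE-high, 1.01 in CS BFUE and 0.410 in CS CFUE. No gene named below needed that floor.

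The comparisons were FACS BFU-E with FACS CFU-E, PE-low with PE-high, PE-low with FACS BFU-E and PE-high with FACS CFU-E. CS BFUE with CS CFUE was added after the cell names were seen. The other 4 comparisons, the gene lists, the naming rule and the alternatives, apart from the added ones named below, were set before the data were examined. Named genes are the 12 with the highest and the 12 with the lowest ratio among genes past 1.5-fold, up to 4 members of each list by size of ratio, and Kit, Tfrc and Cd24a. Some genes that these rules or marker sets name are not reported here. Other genes are said to have been chosen after their values were seen. The 30 lists held 595 entries, 578 of them in the table. They covered early erythroid progenitors, the CFU-E stage, erythroblasts, globins, heme biosynthesis, iron handling, erythroid transcription factors, cytokine receptors, glucocorticoid targets, S phase, G2/M phase, CDK inhibitors and G1 cyclins, the nucleolus, MYC-linked growth, immediate early genes, heat shock, the unfolded protein response, the interferon response, cholesterol biosynthesis, glycolysis, apoptosis and isolation antigens. A further 8 lists held markers of megakaryocytes, mast cells, granulocyte progenitors, monocytes, lymphoid cells, stem cells, hepatocytes and endothelium. Lists overlap, for example in Tfrc and the globins. A list with at least 3 members in a comparison was described by its median log2 ratio, and by the percentile of that median among 10000 random lists of the same size matched in 20 bins of level.

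Cells of each library were clustered with scanpy 1.11.5 (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1). Clusters were called X-like from fixed markers where at least 3 stood 2-fold above the other clusters. Early erythroid progenitor markers were Kit, Gata2, Myb, Cd34, Hpgds, Cd9 and Muc13. CFU-E stage markers were Tfrc, Klf1, Gata1, Epor, Car1, Car2, Ermap, Rhd and Cldn13. Erythroblast markers included Hba-a1, Hba-a2, Hbb-bs, Hbb-bt, Alas2, Slc4a1 and Bpgm. Other cell types used the 8 lists. All clusters not led by markers of other cell types are called erythroid clusters here, including unnamed ones that met no marker rule. The stage score of a cell was its mean log value over the erythroblast and CFU-E stage lists minus that over the early erythroid list. Shares of cells with a UMI were also taken after thinning each cell to 10000 UMIs, which left out 6 CITE-seq cells with no pool and 1 hashed cell named unknown. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, with seed 1.

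No cell was removed as a doublet. Scrublet, run as an alternative, called 2 of 904 hashed cells and 23 of 2453 CITE-seq cells. Of the latter, 8 were among the 195 CS CFUE cells (4.10%) and 0 among the 122 CS BFUE cells. A check on sex-linked genes (at least 2 UMIs of Xist and at least 2 of 4 Y-linked genes) found both in 0 of 902 hashed cells with a pool, which allows up to 0.333% of such cells. The check cannot see doublets of cells of the same sex, so it does not bound all doublets. In CS CFUE it found both in 7 of 195 cells (3.59%, 1.46 to 7.26%). Each pool held cells of both sexes. The comparison was tested on simulated data: Poisson counts from the real levels and depths, with 1 profile shared by all cells of a pool. Such data hold no cell types or other variation between cells, so they check the code and counting error only. In each of the 5 comparisons, 100% of 67 genes set at 2-fold and 66 at 4-fold lay past 1.5-fold in the right direction. Of unchanged genes, 0% did. These numbered 3023 for the FACS pools, 3030 for the PE pools and 2649 for the CS pools. They numbered 3008 for PE-low with FACS BFU-E and 3001 for PE-high with FACS CFU-E. Alternatives changed the fold, the level filter, how cells were combined, centring, the cells used, globins in the total and the clustering. Added ones were those for the CS pools, and others that left out each gene's highest cell or the Scrublet cells or clustered without any list gene. The planned comparison of CD117 and CD71 antibody counts with RNA was not analysed here.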

Results

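The hashed library held 904 cells and 31719814 UMIs, and 902 of its cells carried the name of a pool. FACS BFU-E had 233 cells (7374761 UMIs, median 31594 per cell) and FACS CFU-E 167 (6232350 UMIs, median 38377). PE-low had 208 cells (7084148 UMIs, median 34354) and PE-high 294 (11003022 UMIs, median 38663.5). The CITE-seq library held 2453 cells and 72553258 UMIs. Of these, 122 cells were named CS BFUE (2968491 UMIs, median 23449), 195 were named CS CFUE (7317861 UMIs, median 37589) and 2136 had no pool (62266906 UMIs, median 28855). Cells held between 6863 and 49971 UMIs, and at least 3008 detected genes. The series design asks how erythroid progenitors isolated by 2 methods compare, and the pools allow the 2 stages to be compared within each method and the 2 methods within each stage.

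The FACS BFU-E pool held early progenitor and myeloid transcripts that were near the detection limit in FACS CFU-E, and the FACS CFU-E pool held more of the transcripts of globin, heme and red cell membrane proteins. Mpo, the myeloperoxidase of neutrophil granules, stood at 680 CPM (UMIs of the gene scaled to a common total per pool) in FACS BFU-E and 3.53 in FACS CFU-E, a ratio of 193 (127 to 308), and 75 of 233 FACS BFU-E cells held 99.3% of its UMIs there. Cd34, a surface marker of stem and early progenitor cells, stood at 92.2 against 0.321 (ratio 287, 79.2 to 2377), and Vim, the intermediate filament protein vimentin, at 465 against 1.93 (ratio 241, 138 to 468). Hba-a1, an alpha globin gene, was 40.3-fold higher in FACS CFU-E (27.5 to 61.5), at 147 against 3.66 CPM. Cldn13, a claudin of mouse erythroid cells, was 19.3-fold higher there (15.4 to 24.5), and Sptb, the beta spectrin of the red cell membrane skeleton, 18.6-fold (13.0 to 27.5). Of 3476 genes compared, 333 lay past 1.5-fold higher in FACS BFU-E, 318 higher in FACS CFU-E, and 81.3% lay between. With clusters led by markers of other cell types left out, 256 were higher in FACS BFU-E, 232 of them among the 333. In FACS CFU-E, 253 were then higher, 249 of them among the 318. The count for FACS BFU-E thus rests partly on cells of other types.

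The 12 genes with the highest ratio to FACS BFU-E also held Ctsg and Prtn3, serine proteases of myeloid granules, and Tyrobp and Fcer1g, signalling adaptors of myeloid immune receptors. Ctsg reached 139 against 0.321 CPM (ratio 433, 120 to 3581) and Prtn3 471 against 2.57 (ratio 183, 113 to 321). Ramp1, Ifitm1, Serpinb1a, Tmem176b and Ctla2a made up the 12, with log2 ratios of 8.04, 7.56, 7.52, 7.43 and 7.30. On the FACS CFU-E side stood Rgcc, a regulator of the cell cycle, at 537 against 36.2 CPM, and Hemgn, an erythroid nuclear protein, 11.6-fold higher (9.75 to 14.0). Mrap, C2cd4a, Arhgdig and Tmem56 had log2 ratios of -4.18, -4.88, -3.67 and -3.47. Hba-a2, Hbb-bs and Hbb-bt were higher in FACS CFU-E at log2 ratios of -5.29, -3.90 and -3.71. Hba-a1 and Hba-a2 are near-identical copies, as are Hbb-bs and Hbb-bt, so how reads were split within each pair is uncertain.

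Genes of the antigens CD71, CD24 and CD117 also differed; the gate of each pool is not given in the sources used here, so these differences are not counted as a finding. Tfrc was 3.97-fold higher in FACS CFU-E (3.62 to 4.35) and Cd24a 7.91-fold (7.07 to 8.88), while Kit, the stem cell factor receptor, was 2.28-fold higher in FACS BFU-E (1.98 to 2.64). The isolation antigen list had 3 members compared, with a median log2 ratio of -1.99.

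The erythroid lists separated the 2 sorted pools in both directions. Of 12 early erythroid progenitor genes, 11 were higher in FACS BFU-E and 0 in FACS CFU-E (median log2 ratio 1.54). Muc13, a membrane mucin, stood at 50.7 against 0.481 CPM (ratio 105, 35.8 to 513) and Emb, an adhesion molecule, at 135 against 1.60. Of 23 CFU-E stage genes, 20 were higher in FACS CFU-E (median -1.73). The 1 member higher in FACS BFU-E was Car1, a carbonic anhydrase, with a log2 ratio of 2.32; it was named after its values were seen. Nxpe2 and Rhd, the Rh blood group antigen, were 9.54-fold (8.05 to 11.4) and 8.98-fold (7.96 to 10.2) higher in FACS CFU-E. Of 14 erythroblast genes, 12 were higher in FACS CFU-E (median -2.41), as were 4 of 4 globins (median -4.59). Heme biosynthesis went the same way in 11 of 12 genes (median -1.59). Uros, an enzyme of the heme pathway, stood at 59.5 against 11.1 CPM, and Fech, which inserts the iron, was 3.61-fold higher (3.20 to 4.09). In iron handling, 7 of 12 genes were higher in FACS CFU-E (median -0.71), among them Fth1, the ferritin heavy chain (5500 against 2302 CPM), and Slc25a37, the mitochondrial iron importer (2.80-fold, 2.36 to 3.34).

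Regulators went both ways. Of 19 erythroid transcription factors, 7 were higher in FACS BFU-E and 6 in FACS CFU-E (median -0.30, and -0.08 with clusters led by other cell types left out). Spi1, the myeloid factor PU.1, stood at 91.7 against 3.21 CPM, Mef2c at 120.4 against 9.95, Myb, a factor of immature progenitors, at 371 against 108, and Runx1 at 91.4 against 28.1. Of 5 cytokine receptor and signalling genes, Kit, the kinase Pim1 (1.99-fold, 1.70 to 2.33) and Stat5a (1.58-fold, 1.34 to 1.86) were higher in FACS BFU-E, and Epor, the erythropoietin receptor, was 2.93-fold higher in FACS CFU-E (2.63 to 3.26). In the glucocorticoid list (median -0.34, and -0.04 without those clusters; exposure of these cells to dexamethasone is not given in the sources used here), the metallothioneins Mt2 (5.41-fold, 4.94 to 5.93) and Mt1 (2.05-fold, 1.97 to 2.14) were higher in FACS CFU-E and Zfp36l2, an RNA-binding protein, was higher in FACS BFU-E (2.35-fold, 2.16 to 2.55). Nr3c1, the glucocorticoid receptor, was at a ratio of 1.28 (1.10 to 1.48).

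Cell cycle lists differed less. Of 40 S phase genes, 6 were higher in FACS CFU-E and 0 in FACS BFU-E (median -0.13), led by Ccne1, cyclin E1 (2.65-fold, 2.42 to 2.91), and Rrm2, a subunit of ribonucleotide reductase (1.72-fold, 1.60 to 1.86). Of 37 G2/M genes, 4 were higher in FACS CFU-E (median -0.22), including the mitotic kinase Aurka (1.73-fold, 1.51 to 1.98) and Mki67 (687 against 437 CPM). S phase genes took 0.656% of UMIs in FACS BFU-E, 0.765% in FACS CFU-E, 0.665% in PE-low and 0.799% in PE-high, and G2/M genes 0.938, 1.12, 1.03 and 1.10%. Among 4 CDK inhibitors and G1 cyclins, the G1 kinase Cdk6 (2.39-fold, 2.18 to 2.63) and cyclin D2, Ccnd2 (1.61-fold, 1.46 to 1.77), were higher in FACS BFU-E.

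The glycolysis list (median 0.20) had 4 of 11 genes higher in FACS BFU-E, with Pkm, the pyruvate kinase of most cells, at 437 against 158 CPM and Pgam1 at 413 against 219. Pklr, the pyruvate kinase of red cells and liver, was 4.68-fold higher in FACS CFU-E (4.02 to 5.47). In the unfolded protein and integrated stress response list (median 0.38, and 0.06 with clusters led by other cell types left out), Phgdh, Calr and Sdf2l1 were higher in FACS BFU-E (1.73-fold, 1.68-fold and 1.51-fold), and Asns, asparagine synthetase, was 3.45-fold higher in FACS CFU-E (3.21 to 3.71). All 4 interferon response genes were higher in FACS BFU-E (median 3.56; without those clusters fewer than 3 were compared, so no median was taken), with Ifitm3 at 95.3 against 6.10 and Ifitm2 at 327 against 36.7 CPM. All 6 immediate early and dissociation response genes were higher there (median 1.95), with Jun, an AP-1 transcription factor, at 279 against 31.8 and the inducible chaperone Hspa1a at 68.6 against 15.6. All but Jund entered through FACS BFU-E alone, so their direction followed from the level filter. The whole list, which needs no filter, summed to 1013 against 293 CPM. The nucleolus list had 0 of 29 genes past 1.5-fold (median 0.01) and heat shock 0 of 12 (median -0.04). MYC-linked growth had 2 of 19 each way (median -0.05), with Nme2 at 1548 against 630.4 CPM. In apoptosis 1 of 7 (Casp8, 2.33-fold, 1.92 to 2.83) was higher in FACS BFU-E, and in cholesterol biosynthesis 0 of 2 lay past 1.5-fold.

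**Figure D1:**
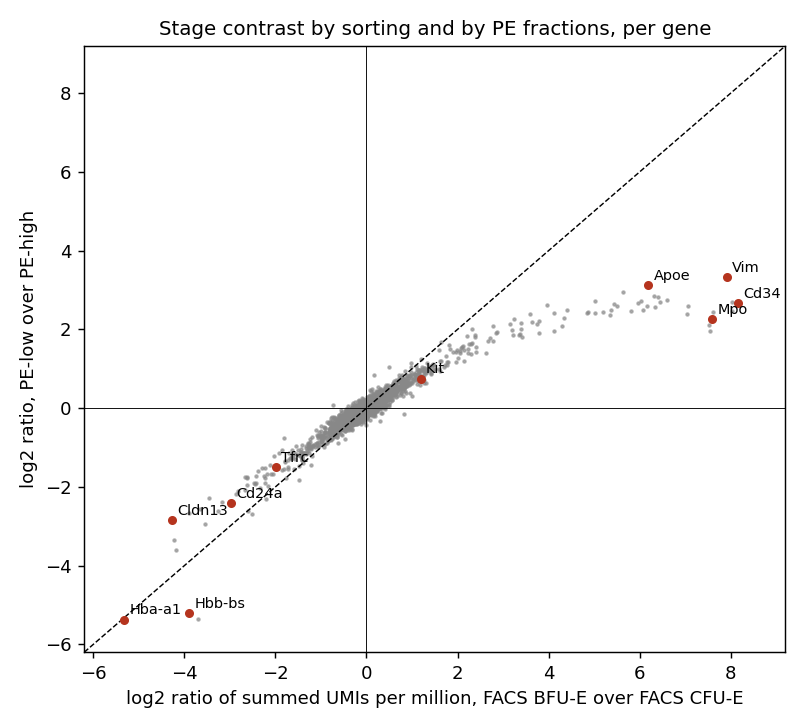
Log2 ratio of pool levels between the early and the late pool. The vertical axis gives PE-low over PE-high, the horizontal axis FACS BFU-E over FACS CFU-E, and each point is a gene compared in both; Hba-a1 and Hbb-bs lie at the lower left, Mpo and Cd34 at the upper right (r 0.925 across genes).

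Markers of other blood cells were higher in the early pool. All 3 granulocyte progenitor genes (median 7.59) and both monocyte genes compared were higher in FACS BFU-E, and so were 3 of 4 stem and multipotent progenitor genes (median 4.07), with the exception of Mllt3 (3.83-fold higher in FACS CFU-E, 3.31 to 4.45). Cd48 stood at 78.6 against 1.93 CPM and Sox4 at 103.6 against 15.1. In megakaryocyte markers, Rap1b alone was compared, at a ratio of 1.49 (1.35 to 1.65). Mast cell, lymphoid, hepatocyte and endothelium markers had 0 genes compared in the hashed pools. Their summed UMIs were 186, 426, 98 and 129 in FACS BFU-E against 2, 122, 19 and 2 in FACS CFU-E. With clusters led by markers of other cell types left out, the list medians became 1.22 for early erythroid genes, -1.37 for the CFU-E stage, -2.05 for erythroblasts, -0.40 for iron handling and 2.07 for stem cell genes.

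PE-low and PE-high differed in erythroid, globin and myeloid genes, as the sorted pools did. PE-high carried 41.3-fold more Hba-a1 (31.4 to 55.5), at 303 against 7.34 CPM, and 41.0-fold more of the beta globin Hbb-bt (33.7 to 50.3). PE-low carried 8.74-fold more Apoe, apolipoprotein E (8.14 to 9.40), with Vim at 452 against 45.2 and Ccnd1, cyclin D1, at 54.4 against 6.45 CPM. Of 3443 genes compared, 239 lay past 1.5-fold higher in PE-low and 201 higher in PE-high, and 87.2% lay between. With clusters led by markers of other cell types left out, 172 were higher in PE-low, 152 of them among the 239. In PE-high, 169 were then higher, 162 of them among the 201.

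Hba-a2 and Hbb-bs were 41.9-fold (25.7 to 73.6) and 37.2-fold (30.8 to 45.2) higher in PE-high. Sptb was 10.1-fold higher (7.72 to 13.6), Hemgn was 7.71-fold higher (6.65 to 8.98) and Cldn13 stood at 182 against 25.1 CPM. Mrap, Rgcc, Nxpe2 and Acp5 were also among the 12, with log2 ratios of -3.60, -2.66, -2.61 and -2.61. On the PE-low side, Emb (7.07-fold, 6.09 to 8.24), Plac8 (6.70-fold, 6.14 to 7.32), Celf2, Gmfg, Igfbp4, Limd2, Ramp1, Psmb8 and Tm6sf1 followed, the last 7 at log2 ratios from 2.94 to 2.68. Tfrc was 2.82-fold (2.61 to 3.06) and Cd24a 5.34-fold (4.87 to 5.87) higher in PE-high, and Kit 1.68-fold (1.49 to 1.90) higher in PE-low.

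Of 10 early erythroid genes, 9 were higher in PE-low (median 1.05), with Cd34 at 88.2 against 13.9 CPM. Of 23 CFU-E stage genes, 20 were higher in PE-high (median -1.50) and Car1, named after its values were seen, was higher in PE-low with a log2 ratio of 2.00. Erythroblast genes were higher in PE-high in 12 of 14 (median -1.97), globins in 4 of 4 (median -5.36), heme biosynthesis in 11 of 13 (median -1.40) and iron handling in 5 of 12 (median -0.52). With clusters led by other cell types left out, the medians became -1.18 for the CFU-E stage, -1.10 for heme, -0.27 for iron and -0.12 for erythroid transcription factors. These factors were split 7 to 5 (median -0.26 with all cells): Spi1 was 5.38-fold (4.57 to 6.36) and Myb 2.27-fold (2.13 to 2.42) higher in PE-low, and Klf1, an activator of globin genes, 2.10-fold (1.99 to 2.23) higher in PE-high. Interferon response genes were higher in PE-low in 4 of 4 (median 2.04, with no median taken for erythroid clusters alone, where fewer than 3 were compared), monocyte genes in 3 of 3 (median 2.44), stem cell genes in 3 of 4 (median 2.04) with the exception of Mllt3 (again with no median for erythroid clusters alone), and both granulocyte genes compared, Mpo (4.77-fold, 4.41 to 5.17) and Prtn3 (4.32-fold, 3.98 to 4.69). S phase genes were higher in PE-high in 3 of 42 (median -0.22) and G2/M genes in 0 of 37 (median -0.06), and 3 of 5 CDK and G1 cyclin genes were higher in PE-low (median 0.67, and 0.33 with clusters led by other cell types left out). The immediate early list had 0 of 1 genes past 1.5-fold (245 against 219 CPM summed), as only Jund passed the level filter here. Below the filter, Jun stood at 13.6 CPM in PE-low against 6.27 in PE-high, and Nfkbia at 18.9 against 7.73. Ier2 stood at 42.5 against 25.4, Hspa1a at 4.94 against 1.45 and Junb at 31.9 against 32.0. Whether this list differs from the sorted pools was not tested. The unfolded protein median was 0.09.

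The 2 stage contrasts, which share no pool, ordered genes alike. Across 3352 genes compared in both, Pearson's r was 0.925 and Spearman's rho 0.917, with genes not independent replicates. Of 298 and 228 genes higher in the earlier pool, 224 were shared, where independent lists would share 20.3, and of 297 and 197 higher in the later pool 192 were shared (17.5 for independent lists). In opposite directions, 0 genes lay past 1.5-fold. The slope of the PE ratios on the FACS ratios was 0.576.

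**Figure D2:**
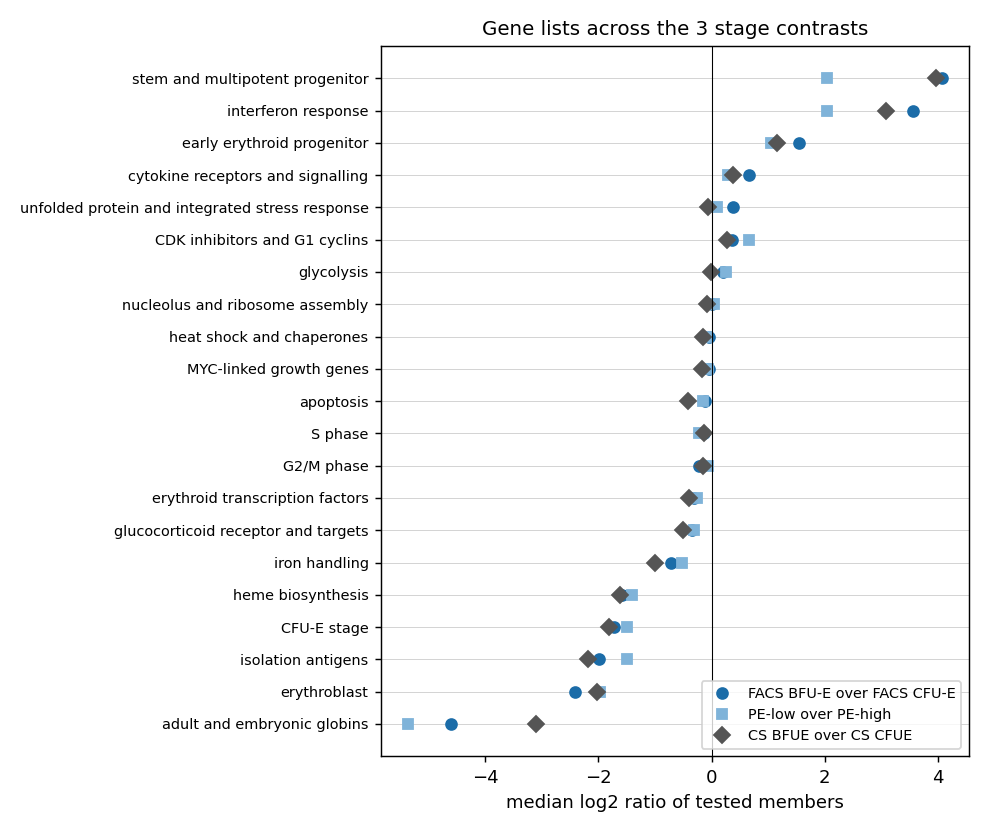
Median log2 ratio of the genes compared in each fixed list with a median in all 3 stage contrasts (points: FACS, PE and CS pools, early over late). Globins lie lowest (-4.59, -5.36 and -3.10) and stem and multipotent progenitor genes lie at 4.07, 2.04 and 3.97.

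PE-low and FACS BFU-E were alike in most genes, and the largest ratios among the genes compared were those of early-response genes. Jun was 20.6-fold higher in FACS BFU-E (16.8 to 25.6), at 279 against 13.6 CPM. Hspa1a was 13.9-fold higher (9.85 to 20.2), and Nfkbia, an inhibitor of NF-kappaB induced by it, 3.87-fold (3.20 to 4.71). Lyz2, the lysozyme of monocytes and macrophages, was 2.27-fold higher in PE-low (1.99 to 2.60), with 27.3% of its PE-low UMIs in 1 cell. Of 3267 genes compared, 10 lay past 1.5-fold higher in PE-low and 16 higher in FACS BFU-E, and 99.2% lay between.

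All 6 immediate early and dissociation response genes compared were higher in FACS BFU-E (median log2 ratio -1.65, below all of the random lists at percentile 0), the others being Ier2 (2.55-fold, 2.23 to 2.92), Jund (2.35-fold, 2.11 to 2.62) and Junb (2.03-fold, 1.73 to 2.39). All but Jund (66.3 CPM in PE-low) entered through FACS BFU-E alone. Their direction followed from the level filter, so neither the count of 6 nor the percentile is separate evidence of it. A UMI of Jun was found in 76.8% of FACS BFU-E cells, 23.1% of PE-low, 41.9% of FACS CFU-E and 17.7% of PE-high cells, and after thinning in 58.8, 10.6, 20.4 and 5.78%. The summed level of all 20 genes of the list, which needs no filter, was 1013 CPM in FACS BFU-E, 245 in PE-low, 293 in FACS CFU-E and 219 in PE-high. Chosen after their values were seen, Fos stood at 42.0 against 2.40 and Egr1 at 23.1 against 3.25 CPM in FACS BFU-E and PE-low.

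**Figure D3:**
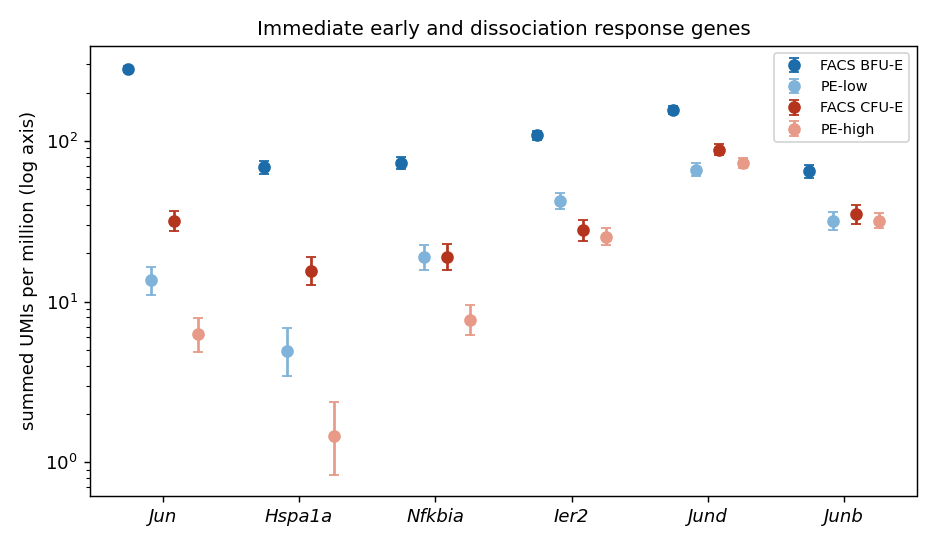
Pool levels of 6 immediate early and dissociation response genes in the 4 hashed pools (log axis, summed UMIs scaled to the UMI total of the pool; bars are 95% exact Poisson intervals). Jun stands at 279 CPM in FACS BFU-E and 13.6 in PE-low, and Hspa1a at 68.6 and 4.94.

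The 3 granulocyte progenitor genes were also higher in FACS BFU-E (median -0.93): Ctsg 3.05-fold (2.69 to 3.47), Mpo 1.91-fold (1.82 to 2.00) and Prtn3 1.53-fold (1.45 to 1.61). Pnrc1, Hist1h2bc, Clk1 and Snhg5 were higher there at log2 ratios of -0.96, -0.79, -0.77 and -0.73. Of 3 monocyte genes, 1 (Lyz2) lay past 1.5-fold in PE-low (median 0.43). Also higher in PE-low were Lsp1 (2.09-fold, 1.84 to 2.38), Rgcc (2.03-fold, 1.75 to 2.36), Ctsc and Ifi30, a cathepsin and a thiol reductase of lysosomes (1.77-fold and 1.75-fold), Kif23, a kinesin of cell division (1.74-fold), Ifitm3 (1.67-fold), Ccnd1 (1.61-fold), Cd52 (1.53-fold) and Rhd (61.7 against 41.1 CPM). With clusters led by other cell types left out, 3 genes in place of 10 were higher in PE-low. Early erythroid genes had 0 of 12 higher in PE-low and 2, Cd63 and Lmo4, higher in FACS BFU-E (median -0.27). The CFU-E stage list had a median of 0.19 with 1 of 14 past 1.5-fold (Rhd), and G2/M a median of 0.18 with 1 of 36 (Kif23). Tfrc, Cd24a and Kit had log2 ratios of 0.39, 0.58 and -0.32. Heme, iron, S phase, MYC-linked, nucleolus, heat shock, glycolysis and apoptosis lists had 0 members past 1.5-fold. Stem cell genes had a median of -0.23.

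PE-high and FACS CFU-E were also alike in most genes, and most exceptions were higher in PE-high. Prtn3 stood at 71.3 against 2.57 CPM (ratio 27.8; 31.6% of its PE-high UMIs lay in 1 cell) and Mpo at 74.8 against 3.53 (ratio 21.2, 13.9 to 34.0). The 4 globins were higher in PE-high, from 3.80-fold for Hbb-bs (3.55 to 4.06) and 3.58-fold for Hbb-bt (3.36 to 3.83) to 2.06-fold for Hba-a1 (1.91 to 2.22) and 1.79-fold for Hba-a2 (1.58 to 2.03). Of 3257 genes compared, 23 lay past 1.5-fold higher in PE-high and 4 higher in FACS CFU-E, and 99.2% lay between. Without the 25% of cells with the fewest UMIs, 14 genes in place of 23 were higher in PE-high.

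Plac8, a protein of myeloid and progenitor cells, was 16.7-fold higher in PE-high (10.8 to 27.1), Apoe 7.99-fold (6.19 to 10.5), Cmtm7 5.18-fold (4.23 to 6.41) and Tmsb4x, an actin-binding thymosin, 4.26-fold (3.86 to 4.70). Arhgdib, Cyba, H2afy and S100a10 followed with log2 ratios of 1.55, 1.38, 1.35 and 1.30. Higher in FACS CFU-E were C2cd4a (1.98-fold, 1.69 to 2.31), Snhg12, Snhg5 and Clk1 (log2 ratios of -0.73, -0.67 and -0.64). At least 5 UMIs of Mpo were found in 17 of 294 PE-high cells, which held 94.0% of its UMIs, in 75 of 233 FACS BFU-E cells and in 0 of 167 FACS CFU-E cells. At least 5 UMIs of Hbb-bs were found in 86 of 294 PE-high and 46 of 167 FACS CFU-E cells, and the highest cell held 751 and 154.

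In lists, the globin median was 1.44 (percentile 100), and 4 of 14 erythroblast genes, the globins, were higher in PE-high (median 0.10). The CFU-E stage list had 0 of 22 past 1.5-fold and a median of -0.19, below all of the random lists (percentile 0). Heme and iron medians were -0.12 and -0.08, S phase 0.05, G2/M 0.01, CDK and G1 cyclins 0.19 and heat shock 0.07, with 0 members past 1.5-fold. Ifitm2, the interferon response gene compared, was 1.72-fold higher in PE-high (1.48 to 2.00). Tfrc and Cd24a had log2 ratios of -0.10 and 0.01. Across 2957 genes, the ratios of the 2 method contrasts had Pearson's r of 0.0338 and Spearman's rho of 0.185. Clk1 and Snhg5 were lower in the PE pool in both contrasts, and Mpo and Prtn3 went opposite ways.

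CS BFUE and CS CFUE, compared after their names were seen, differed in erythroid, globin and myeloid genes, as the sorted pools did. Mpo was 55.3-fold higher in CS BFUE (40.4 to 77.5) and Cd34 stood at 105 against 2.60 CPM (ratio 40.6, 25.6 to 68.4). Cldn13 was 22.2-fold (14.6 to 35.6) and Hba-a1 16.4-fold (12.1 to 22.7) higher in CS CFUE. Of 3077 genes compared, 270 lay past 1.5-fold higher in CS BFUE and 330 higher in CS CFUE, and 80.5% lay between. With clusters led by other cell types left out, 173 in place of 270 were higher in CS BFUE, and the medians became -1.32 for the CFU-E stage and -1.43 for erythroblasts. The median of the glucocorticoid list was -0.51 with all cells and 0.01 without those clusters.

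Alox5ap (ratio 136, 45.6 to 664), Tespa1 (125, 41.9 to 612) and Adgrl4 (90.2, 38.0 to 281) had the highest ratios to CS BFUE, followed by Serpinb1a, Tmem176b, Ctsg, Klk8, Ctla2a and Tyrobp at log2 ratios from 6.09 to 5.27. Higher in CS CFUE were Mrap (50.4-fold, 17.1 to 245.7), Tmem56 (20.7-fold, 11.5 to 41.6), Rgcc (16.0-fold, 12.5 to 20.7), Nxpe2 (11.8-fold, 8.77 to 16.3), Sphk1 (73.8 against 6.74 CPM), Sptb, Hba-a2 and Rhd, with Arhgdig and Asb17os at log2 ratios of -3.88 and -3.60. Early erythroid genes were higher in CS BFUE in 10 of 11 (median 1.16), and CFU-E stage genes higher in CS CFUE in 21 of 22 (median -1.82), with Car1, named after its values were seen, at a log2 ratio of 1.69. Medians were -2.03 for erythroblasts, -3.10 for globins, -1.63 for heme, -0.99 for iron and 3.07 for the interferon response. The immediate early list had 0 of 1 genes past 1.5-fold, as only Jund passed the level filter here, and summed to 262 against 183 CPM. Below the filter, Jun stood at 33.0 CPM in CS BFUE against 6.70 in CS CFUE, Nfkbia at 20.2 against 6.83 and Ier2 at 40.8 against 19.0. Hspa1a stood at 8.08 against 8.06 and Junb at 15.5 against 20.2. Whether this list differs from the sorted pools was not tested. Medians were -0.06 for the unfolded protein list and -0.01 for glycolysis. Ccne1 was 4.01-fold higher in CS CFUE (3.23 to 5.02). Tfrc and Cd24a were 4.71-fold (4.03 to 5.53) and 4.52-fold (3.90 to 5.27) higher in CS CFUE, and Kit 1.68-fold (1.46 to 1.92) higher in CS BFUE. The liver markers Alb and Afp were higher in CS CFUE (51.9 against 9.43 and 57.9 against 13.8 CPM), where 2 cells held 73.4% and 77.1% of their UMIs. Across 2997 genes, the CS and FACS ratios had Pearson's r of 0.964 and Spearman's rho of 0.892, and 223 and 232 genes were shared (22.8 and 28.6 for independent lists).

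Along the stage score, which rises with CFU-E and erythroblast transcripts, the pools fell into an early and a late group. Medians were -0.119 in FACS BFU-E (SD over cells 0.284), -0.0816 in PE-low (0.274) and -0.0894 in CS BFUE (0.262). They were 0.540 in FACS CFU-E (0.143), 0.482 in PE-high (0.372) and 0.477 in CS CFUE (0.137). Of PE-high cells, 98 of 294 (33.3%) scored below the 5th percentile of FACS CFU-E, as did 25 of 195 CS CFUE cells (12.8%). Of PE-low cells, 26 of 208 (12.5%) scored above the 95th percentile of FACS BFU-E. All cells of a pool were scored, including those in clusters led by markers of other cell types. These were 62 cells in FACS BFU-E, 53 in PE-low and 17 in PE-high. A low score therefore need not mean an early erythroid stage.

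**Figure D4:**
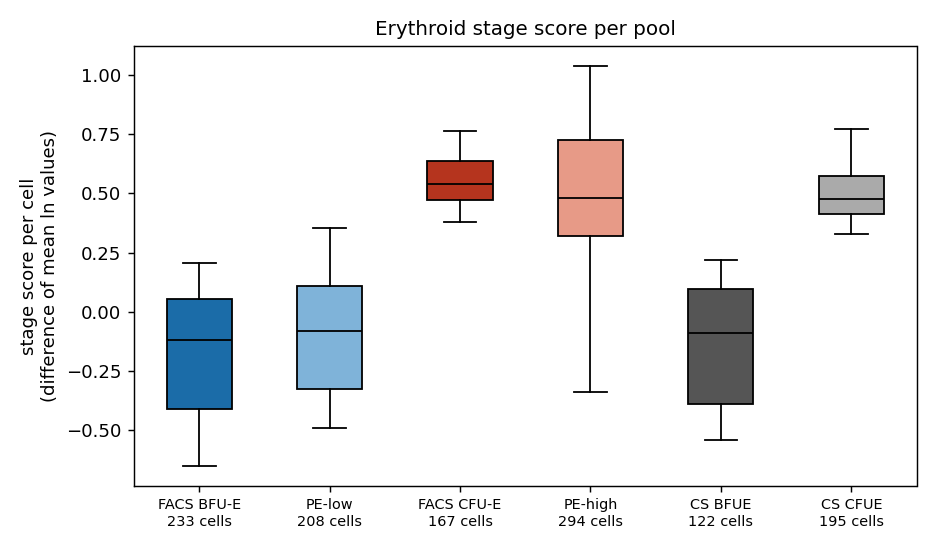
Stage score per cell (difference of mean log values, no unit) in 6 pools. Boxes give the median and quartiles over cells; FACS CFU-E lies between quartiles of 0.471 and 0.637 and PE-high between 0.320 and 0.725.

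Cells of other types, by clusters led by their markers, made up 26.6% of FACS BFU-E (62 of 233, 21.1 to 32.8%), 25.5% of PE-low (53 of 208, 19.7 to 32.0%), 5.78% of PE-high (17 of 294, 3.40 to 9.10%) and 0.599% of FACS CFU-E (1 of 167, 0.0152 to 3.29%). Clustered without any list gene, the counts were 63, 54, 17 and 1. These clusters were stem and multipotent progenitor-like, at 18.5, 14.9, 3.74 and 0.599% of the pools in that order, and monocyte and macrophage-like, at 8.15, 10.6, 2.04 and 0%, where 0 of 167 cells allows up to 2.18%. In the CITE-seq library, clustered on its own, the share was 37.7% of CS BFUE (46 of 122, 29.1 to 46.9%) and 1.54% of CS CFUE (3 of 195, 0.318 to 4.43%).

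**Figure D5:**
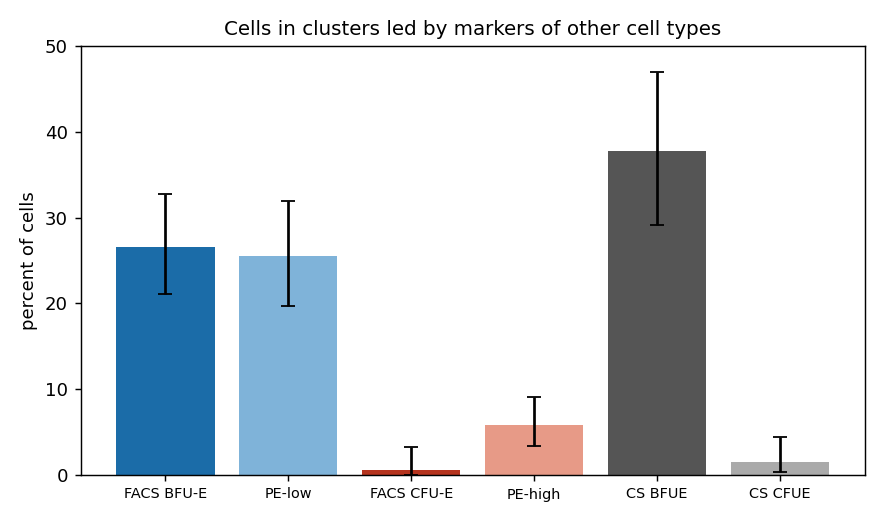
Percent of cells in clusters led by markers of other cell types, in 6 pools, with 95% exact Clopper-Pearson intervals. FACS BFU-E (26.6%) and PE-low (25.5%) overlap, and PE-high (5.78%) lies above FACS CFU-E (0.599%).

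In the GRCm38 assembly, Mpo lies on chromosome 11 from 87793784 to 87804412 (ENSMUSG00000009350) and Prtn3 on chromosome 10 from 79879667 to 79883174. Hba-a1 (32283672 to 32284486) and Hba-a2 (32296492 to 32297310) lie side by side on chromosome 11, and Hbb-bt (103812524 to 103813923) and Hbb-bs (103826523 to 103827928) on chromosome 7. Ifitm2 (140954837 to 140959686), Ifitm1 (140967429 to 140969827) and Ifitm3 (141009590 to 141010744) also neighbour each other on chromosome 7. Jun lies on chromosome 4 from 95049036 to 95052222 (ENSMUSG00000052684), Kit on chromosome 5 from 75574987 to 75656722 and Tfrc on chromosome 16 from 32608896 to 32632794. All counts are per whole gene from 3' ends.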

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

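Of the tests below, those on single clusters, on a few cells with very high levels, on the sorting step, on doublets for Mpo and Prtn3, on free globin RNA and on the stage range were chosen only after the result was seen.

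The immediate early and dissociation response genes were higher in FACS BFU-E than in PE-low (median log2 ratio of PE-low over FACS BFU-E -1.65). The whole list, which needs no level filter, summed to 1013 CPM in FACS BFU-E and 245 in PE-low. Of the 6 genes compared, all but Jund entered through FACS BFU-E alone, so the sign of this median followed from the filter. In erythroid clusters alone the same 6 genes had a median of -1.98, all of them past 1.5-fold (-1.54 over the 5 that pass the filters there), and in the 3 such clusters with at least 20 cells of each pool it was -2.26, -2.19 and -1.77 (the first also carried megakaryocyte markers, the other 2 no markers of other types but no name), which argues against a different share of other cell types. With the highest 10% of cells left out for each gene the median was -1.40, which argues against a few cells with very high levels. A response to the sorting step stays open: PE-high over FACS CFU-E had a median log2 ratio of -0.79 over the 6 genes. Of these, 3 lay past 1.5-fold higher in FACS CFU-E: Jun (-2.34), Hspa1a (-3.42) and Nfkbia (-1.31). Jund (-0.27), Junb (-0.13) and Ier2 (-0.13) did not. The 5 genes other than Jund did not reach 50 CPM in either pool, and the whole list summed to 219 against 293 CPM. Sorting and pool cannot be told apart here, as each isolation is 1 pool, and no biological explanation was tested.

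Mpo and Prtn3 stood out because the method contrasts went opposite ways: the log2 ratios were -0.93 and -0.61 for PE-low over FACS BFU-E, and 4.41 and 4.80 for PE-high over FACS CFU-E. The difference between these contrasts was not tested. For the higher level in PE-high, 83.3% of the UMIs of both genes lay in 17 cells of other types, which argues against free RNA as the whole cause; the other PE-high cells held 25.4 CPM, or 7.83 without 4 cells that had at least 5 UMIs, against 6.10 in FACS CFU-E, and the source of this rest stays open. Of the UMIs of both genes, 4.98% lay in PE-high cells with a CFU-E stage level at least 30% of the way from cells of other types in PE-low to the other PE-high cells, a level that 92.5% of all PE-high cells had, which argues against doublets with an erythroid cell as the main source. The 19 PE-high cells with at least 5 UMIs of both genes together held 94.8% of these UMIs. Of them, 0 reached that level and 4 lay outside clusters of other types. The 17 cells of other types had a median CFU-E stage level of 211 CPM, against 7480 in the other PE-high cells. Most of these UMIs thus lay in cells low in CFU-E stage transcripts. Whether whole cells of other types are the only source, and why the pool held them, stays open. Such cells held 4.08% of PE-high UMIs. For 33 other abundant transcripts of such cells, the median excess was 1.05 times (quartiles 0.930 to 1.22) what that share would need. Such cells were grouped by expression and alone brought 0.937 times that need, so this test had little room to come out otherwise.

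The globins were higher in PE-high than in FACS CFU-E. The 30 PE-high cells with the most globin held 67.1% of it, and the median cell held 151 CPM in PE-high and 266 in FACS CFU-E, which argues against free RNA. In these 30 cells the Kit and Myb level was 0.0938 of that in the other PE-high cells (0.0579 to 0.144), which argues against doublets of a CFU-E stage cell with an erythroblast. A later stage range in PE-high stays open: with the globins left out of the stage score, 46 of 294 cells (15.6%) scored above the 95th percentile of FACS CFU-E and 92 (31.3%) below its 5th percentile. All PE-high cells were scored, 17 of them in clusters led by markers of other cell types, so a low score need not mean an earlier erythroid stage. Stage range and isolation method cannot be told apart with 1 pool each.

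The CITE-seq cells with no pool, which no comparison used, held 227 CPM of the monocyte and macrophage list and 26.0 of the endothelium and stroma list, above the 0.0482 CPM that a count of 0 allows and above the CS pools (144 and 14.8 in CS BFUE). PE-low held more of both lists (351 and 87.9 CPM), so the summed levels are not peculiar to cells with no pool. The cells behind the sums can differ. C1qa, a macrophage gene, had 0 UMIs in PE-low, while 13 cells with no pool formed a cluster led by C1qb, Cd5l and C1qa.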

How the results depend on the processing

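Chosen after the data were seen were all alternatives for the CS pools and those without each gene's highest cell, without Scrublet doublets and without any list gene in the clustering. No list median past 1.5-fold took the other sign, but the order of shares and the balance of counts turned in places, as given below. Medians within 1.5-fold could take the other sign: in erythroid clusters alone that of the glucocorticoid list in the CS pools passed from -0.51 to 0.01, and that of the unfolded protein list in the PE pools from 0.09 to -0.14. Of the 171 values for counts, lists past 1.5-fold, shares, agreement and stage scores, 122 stayed within the limits set for them and 49 moved. The limit was 1.5-fold of the main value for counts and the main interval for shares. For differences in median stage score it was the SD over cells. That SD was wider than the differences between methods within a stage, so it could not show whether those differences hold. Of 312 list medians, 293 stayed and 19 moved. Centring, means over cells, thinning, globins left out, each gene without its highest cell and no Scrublet doublets moved 0 of the first kind. The correlation of the FACS and PE stage contrasts ranged from 0.917 to 0.946.

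Counts of genes follow the fold and filter by construction. They are given as higher in the first pool and in the second, at 2-fold, at 20 CPM, at 200 CPM, and with no filter and a pseudocount of 1 CPM. FACS BFU-E with FACS CFU-E: 184 and 145, 817 and 565, 61 and 79, 2732 and 1079. PE-low with PE-high: 117 and 100, 582 and 386, 53 and 52, 2578 and 807. PE-low with FACS BFU-E: 3 and 7, 28 and 48, 0 and 3, 585 and 377. PE-high with FACS CFU-E: 15 and 0, 59 and 11, 5 and 0, 759 and 164. CS BFUE with CS CFUE: 147 and 143, 697 and 592, 49 and 66, 3800 and 1182. Centred, it was 310 and 264, against 270 and 330 uncentred, so the balance turned with each count within its limit. In erythroid clusters alone, 3 genes were higher in PE-low than in FACS BFU-E, 1 list lay past 1.5-fold there, and 173 genes were higher in CS BFUE. Without the 25% of cells with fewest UMIs, 14 genes were higher in PE-high than in FACS CFU-E. The share of erythroblast-like cells was 4.19% in FACS CFU-E and 15.3% in PE-high, from different clusters: 6 of the 7 FACS CFU-E cells formed a cluster of their own (median 15470.5 UMIs), apart from the 45 PE-high cells. It was 11.98% and 26.2% at resolution 0.5. In FACS CFU-E it was 1.198% clustered without cell cycle genes and 28.1% without any list gene, where PE-high had 14.3%, so the order of the 2 pools turned. In PE-high it was 28.2% at resolution 1.5. For these cell choices and shares the cause was not tested.

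No paired analysis was possible because each pool is 1 sample. Depth limits genes near the floor: with 3 counts or fewer in a pool the ratio is poorly fixed, as for Cd34 in the FACS pools (79.2 to 2377). The alternatives for CD117 and CD71 antibody counts were not run.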

Other observations

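No test in this part was planned; the values below were chosen after they were seen. Among CITE-seq cells with no pool, 58 formed a cluster led by Lyz2, Ccr2 and Tyrobp, genes of monocytes, and 13 formed a cluster led by C1qb, Cd5l and C1qa, genes of tissue macrophages. Both clusters held 0 cells of CS BFUE and 0 of CS CFUE. Marco, a scavenger receptor of macrophages, stood at 10.7 CPM in the cells with no pool and at 0.410 in CS CFUE.

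The mast cell list summed to 25.2 CPM in FACS BFU-E (21.7 to 29.1), 14.1 in PE-low (11.5 to 17.2), 7.27 in PE-high (5.77 to 9.05) and 0.321 in FACS CFU-E (0.0389 to 1.16). The megakaryocyte list summed to 248 CPM in FACS BFU-E, 247 in PE-low, 132 in PE-high and 111 in FACS CFU-E. The endothelium and stroma list summed to 87.9 CPM in PE-low (81.2 to 95.1) and 17.5 in FACS BFU-E (14.6 to 20.8).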
